A study of Homo sapiens with 12 samples.

How the data were processed

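Polyadenylated RNA was sequenced from 2 lymphoma cell lines, JeKo-1 and Granta-519, each treated with 4 µM chidamide or with vehicle for 12 h, per the labels' protocols. The labels gave 3 libraries for each of the 4 groups, 12 in all, and groups and replicate numbers were taken from the library titles. The labels did not say whether replicates came from separate cultures, so p-values measure only the spread between these libraries, which may be technical. No spike-in RNA was named, so levels are relative to the rest of each library and a change in total RNA per cell was not measurable.

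The authors deposited a table of whole-number counts per gene symbol. Reads were aligned with STAR to the hg19 build, per the submitters' processing notes. The STAR version, the counting tool, the gene annotation and the strand setting were not given in the sources used here. A gene and an overlapping or antisense gene could therefore share reads, and near-identical copies (HSPA1A and HSPA1B, the HLA genes, ribosomal protein genes with their pseudogenes) are uncertain. The table held 26364 genes. Of these, 4719 had no count in any library, and 28 had names turned into dates by a spreadsheet, 4 of them sharing a name. The date-like names held 0.26% of all counts; they were kept in the totals and are not named here. No gene of the mitochondrial genome was listed. Library totals ran from 12873642 to 16592694 counts. Between replicates of a group, a chi-square over genes averaged 1.65 to 5.96 per gene, so no 2 libraries were alike within sampling noise and none was merged. The highest values involved vehicle replicate 2 of the libraries labelled JeKo-1.

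The authors also deposited a second table, named as TPM, whose values are a length-scaled score and not TPM. Its columns summed to 81790 to 84121, each to a different total, whereas TPM has the same fixed total in every library. For every gene with 20 or more counts the deposited value was the count divided by a constant of that gene and by the rounded library total, to a relative tolerance of 0.0001. How the constant was made was not given in the sources used here. These scores were used only as an alternative input, and 6 further unnamed columns held no values.

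Differences were tested with edgeR 4.0.16 in R 4.3.3 on the deposited counts: filterByExpr by group, TMM scaling, robust glmQLFit with 4 group means, and glmQLFTest. The 12 libraries shared 1 fit with 8 residual degrees of freedom. The contrasts were chidamide against vehicle in each line, the difference between these 2 effects, and the 2 lines in vehicle. Of all genes, 15087 were tested, and p-values were adjusted by Benjamini-Hochberg over them with a threshold of 0.05. The common biological coefficient of variation was 0.0422, so that small changes passed the threshold. CPM values used TMM-scaled library sizes. The SE given with a log2 change was the absolute log2 change divided by the square root of the test's F. It is back-calculated and only approximate, above all where counts are few. A fold against a group with 0 counts was computed against 3 counts over the group, with TMM-scaled library sizes, and is given as a lower bound. Such bounds cover counting error only.

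Before the data were examined, 38 gene lists were fixed for a histone deacetylase inhibitor in B-cell lymphoma, among them markers of T and natural killer cells, myeloid cells, erythroid and megakaryocytic cells, and epithelial and stromal cells. The 35 lists with 5 or more tested genes were tested with camera (limma 3.58.1, preset correlation of 0.01, two-sided) and adjusted over the 35 by Benjamini-Hochberg. Camera compares a list with the other genes. The estimated correlation per list and fry, which asks whether the genes of a list move one way on balance, were alternatives. Counts of genes that rose or fell use the adjustment over all tested genes. Adjusted over the list alone, those within a line were the same except as follows. In the libraries labelled JeKo-1, 36 ribosomal protein genes rose, 15 genes of cyclins and their kinases fell, 10 genes of the stress responses fell, 8 neuronal genes rose and 2 T-cell and natural killer markers rose. In Granta-519, 19 histone deacetylase inhibitor markers rose, 21 autophagy and lysosome genes fell, and 8 epithelial and stromal markers rose. Of the counts given for the difference between lines, that of interferon-stimulated genes with a more positive change under the JeKo-1 label became 22. The lists of replication-dependent histones (4 tested genes), erythroid and megakaryocytic markers (2) and mitochondrial transcripts (0) were too small to test. Of 38 fixed neuronal genes 22 were tested, and of 21 myeloid markers 9. Of 21 T-cell and natural killer markers 8 were tested, and of 21 epithelial and stromal markers 11. A gene silent in all groups left the list, whereas one high in chidamide alone could pass the filter. Shares of tested genes that rose in these lists therefore do not hold for the lists as fixed. Some tested list genes had no count in any library of a line and could not change there. Under the JeKo-1 label these were 6 markers of histone deacetylase inhibition, 3 neuronal genes, 2 p53 targets and 1 each of the MYC network, inhibitors of apoptosis, CDK inhibitors, B-cell transcription factors, interferon-stimulated genes, T-cell and natural killer markers and myeloid markers. In Granta-519 they were 2 CDK inhibitors, 1 neuronal gene and 1 gene of the REST complex.

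The rule for naming genes was also fixed before the data were examined. It took 9 genes whatever their change (MYC, BCL2, BCL6, CCND1, CDKN1A, HDAC1, HDAC2, HDAC3, HDAC10). For each line it took the 6 largest rises and 6 largest falls among genes past the threshold with a mean of 10 CPM or more in a group and no overlap between replicates. Separation of 3 from 3 values has a chance of 10%. It took the 5 largest differences between lines in each direction. From each list it took up to 3 genes with the smallest p per line and any that moved against the others. For the lines in vehicle it took 5 list genes in each direction. Some genes that the rule took are not reported here. Agreement between the lines was described by Pearson and Spearman correlation of log2 fold changes across genes, which are not independent replicates, and by shared calls against the product of the 2 call counts divided by the genes tested. The lines share no control library.

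The pipeline was tested on simulated counts drawn from the real means and library sizes, with 100 genes changed 1.5-fold and 100 changed 2-fold in each line. Over 14777 tested genes edgeR recovered 87% and 99% of these in the libraries labelled JeKo-1 and 82% and 95% in Granta-519. It recovered 68.5% and 84.5% of 200 differences between the lines at each size. Of 14317 unchanged genes it called 9, 14 and 13 in the 3 comparisons. Few genes changed in this simulation, and as many were raised as lowered apart from the MYC target list. In the real data 10016 and 10695 of 15087 genes were called, and 2-fold changes were mostly rises. These rates therefore do not cover scaling where most genes change or where rises outnumber falls. In the same simulated counts the MYC target list was shifted under the JeKo-1 label only: camera called it, with 2 of 35 lists called in all, and 0 in the other line. Simulated genes were drawn independently of each other. These list calls therefore do not show how often camera errs where the genes of a list are correlated.

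Alternatives fixed before the data were examined were RLE, upper-quartile and library-size scaling; no count filter, or a filter of 1 CPM in 3 libraries; DESeq2 1.42.0; the replicate number as a block; the groups of a contrast fitted alone; a 2-fold threshold; leaving out each library in turn; and limma-trend on the length-scaled score as log2(score + 1) or log2(score + 0.1), with a mean score of 0.5 or more or with no filter. Thinning every library to the lowest total, and list tests on genes with a count in the line (for the difference, in both lines), were added after seeing the data. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9 prepared tables and plots. Gene lengths came from GENCODE release 29, an annotation of a different build from the authors', so no coordinates are given.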

Results

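The response of B-cell lymphoma cells to chidamide, a benzamide that inhibits the histone deacetylases HDAC1, HDAC2, HDAC3 and HDAC10, was measured by sequencing polyadenylated RNA. JeKo-1 and Granta-519 are established lines from mantle cell lymphoma, a B-cell cancer in which a translocation usually activates the cyclin gene CCND1. Each line was given 4 µM chidamide or vehicle for 12 h, and each of the 4 groups held 3 libraries with totals of 12873642 to 16592694 counts. The title of the series concerns lymphomas with high MYC and BCL2 and an effect of the drug through MYC. Libraries labelled JeKo-1 had 0 counts of SOX11, a transcription factor gene typical of mantle cell lymphoma, in both groups, and 5 counts of CCND1 over the 3 vehicle libraries. Granta-519 vehicle libraries held 157 ± 7.52 CPM of SOX11 and 2114 ± 43.0 CPM of CCND1 (SD, n = 3). Both genes are known in JeKo-1 cells, so those libraries are called by their label throughout.

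The first comparison asked how 12 h of chidamide changed expression under the JeKo-1 label. MYC, the transcription factor that drives growth genes, fell from 329 ± 8.48 to 203 ± 5.91 CPM (SD, n = 3), and 58 of 60 tested MYC target genes fell with it. CDKN1A, which encodes the cell-cycle inhibitor p21, rose 3.41-fold from 32.9 ± 1.82 CPM. BCL2, the antiapoptotic gene, rose from 23.5 ± 0.61 to 42.1 ± 1.32 CPM. Interferon-stimulated genes rose as a group, while DNA replication genes fell. NF-kB targets and surface antigens also rose and heat shock genes fell by camera, calls lost with an estimated correlation (adjusted p = 0.0502, 0.0502 and 0.0511). Of 15087 genes tested, 5320 were higher and 4696 lower after chidamide, 10016 in all (edgeR's quasi-likelihood test, Benjamini-Hochberg). Changes of at least 2-fold were mostly rises, with 2587 genes higher and 400 lower.

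On the log2 scale MYC changed by −0.70 ± 0.04 (SE; edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p = 3.03e-21), CDKN1A by 1.77 ± 0.06 (edgeR adjusted p = 2.93e-33) and BCL2 by 0.84 ± 0.06 (edgeR adjusted p = 1.02e-17). BCL6, the master repressor of germinal-centre B cells, moved little, from 234 ± 10.5 to 213 ± 1.83 CPM, a log2 change of −0.14 ± 0.05 (edgeR adjusted p = 0.00601). CCND1 went from 5 to 44 counts over 3 libraries, 2.83 ± 0.46 on the log2 scale. Among the drug's targets, HDAC10 fell from 48.1 ± 0.68 to 22.5 ± 3.33 CPM, a log2 change of −1.10 ± 0.08 (edgeR adjusted p = 1.55e-17). HDAC2 rose by 0.31 ± 0.04 and HDAC3 by 0.15 ± 0.05, while HDAC1 stood at 536 ± 7.54 CPM in vehicle and 566 ± 9.82 CPM after the drug, a change of 0.08 ± 0.04 that did not pass (edgeR adjusted p = 0.0664).

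**Figure D1:**
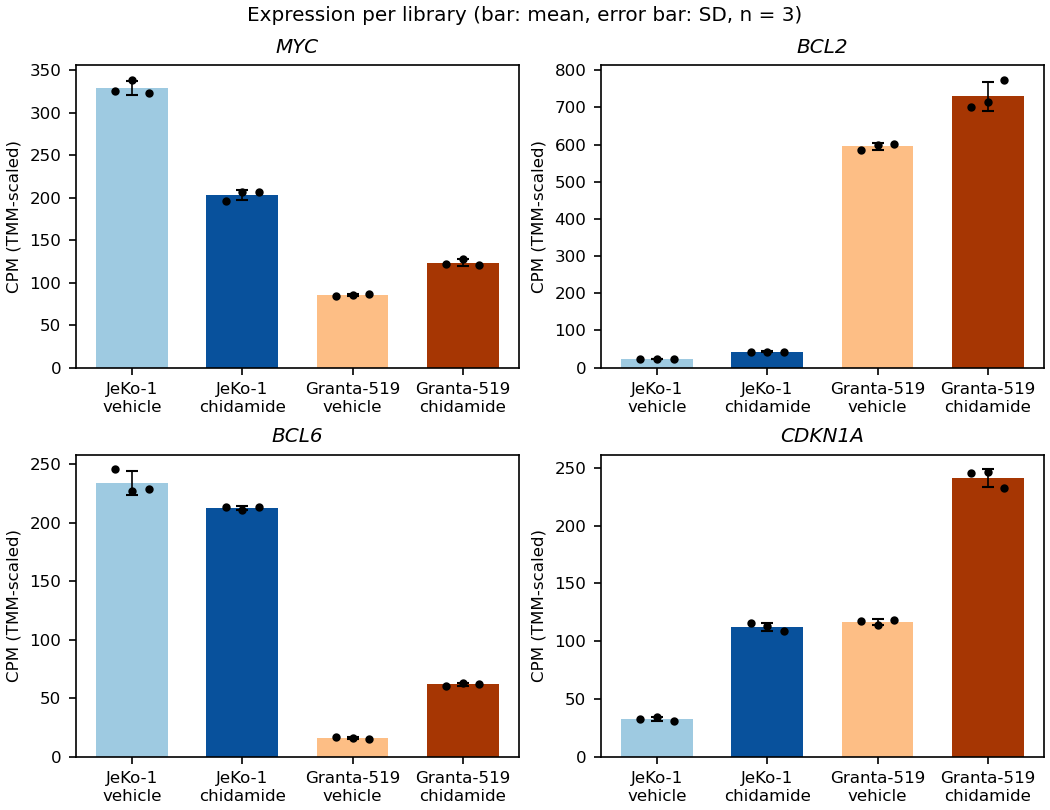
Expression of MYC, BCL2, BCL6 and CDKN1A in TMM-scaled CPM on linear axes from 0, by line label and treatment; bars are group means, error bars SD and points the 3 libraries of each group. MYC lies lower after chidamide under the JeKo-1 label (329 to 203 CPM) and higher in Granta-519 (85.1 to 123.5 CPM), while CDKN1A lies higher in both.

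The largest rises under the JeKo-1 label included FMN1, a formin that nucleates actin filaments, from 9 to 555 counts over 3 libraries (log2 change 5.67 ± 0.25). LBH, a transcription cofactor gene, rose by 4.92 ± 0.22 and GPR158, a G-protein-coupled receptor gene, by 4.84 ± 0.32. CXCL10, an interferon-induced chemokine, rose from 4.11 ± 0.64 to 93.3 ± 6.89 CPM (4.49 ± 0.10). LOC105747689 (4.36 ± 0.22) and C12orf79 (4.26 ± 0.22) completed the 6. The largest fall was in KCTD15, which encodes a BTB-domain protein, from 71.4 ± 1.13 to 14.6 ± 0.31 CPM (−2.29 ± 0.08). NAGPA, the enzyme that uncovers the lysosomal sorting signal, changed by −2.19 ± 0.18 and TFAP4, a transcription factor gene induced by MYC, by −1.94 ± 0.08. STRA13 (−1.88 ± 0.07), CTSA, the lysosomal cathepsin A (−1.84 ± 0.08), and DNLZ, a mitochondrial chaperone escort gene (−1.78 ± 0.11), followed. Each of these 12 genes had an adjusted p of 2.07e-16 or lower by edgeR's quasi-likelihood test.

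Among lists of growth genes under the JeKo-1 label, no MYC target rose, and the median log2 change of the 60 was −0.77 (camera, Benjamini-Hochberg adjusted p = 3.95e-26). The uracil glycosylase gene UNG fell from 186 to 64.6 CPM, the nucleolar repressor gene MYBBP1A from 293 to 113 CPM and the growth regulator gene PA2G4 from 679 to 352 CPM. Of 45 DNA replication genes 35 fell and 6 rose (camera adjusted p = 4.24e-08). MCM7, MCM5 and MCM4, subunits of the replicative helicase, led the falls (1273 to 592 CPM for MCM7), against rises in RFC1, a clamp loader gene, and TK1, thymidine kinase. Of 23 cyclin and kinase genes 14 fell, among them CDK4, E2F1 and CCNA2, and 7 rose, among them the retinoblastoma gene RB1 and CDK1 (camera adjusted p = 0.0155; adjusted p = 0.0511 with an estimated correlation). The median of this list was −0.28 and its mean 0.06, so these differed in sign. CDK inhibitor genes rose (5 up, 1 down of 8; camera adjusted p = 0.0121; adjusted p = 0.0956 with an estimated correlation), including CDKN2D from 10.6 to 24.0 CPM and CDKN1B from 12.1 to 22.6 CPM.

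Metabolic and chaperone lists fell under the JeKo-1 label. Of 14 heat shock genes 12 fell, such as HSPD1 (1942 to 1426 CPM) and HSPA8 (3740 to 2740 CPM), while the cochaperone gene BAG3 rose from 0.81 to 6.18 CPM (camera adjusted p = 0.000247; adjusted p = 0.0511 with an estimated correlation). Glycolysis genes fell in 15 and rose in 4 of 24, with GPI, LDHA and ALDOA down and the glucose transporter gene SLC2A3 up from 1.26 to 9.97 CPM (camera adjusted p = 0.0023; adjusted p = 0.174 with an estimated correlation). Oxidative phosphorylation genes fell in 25 and rose in 3 of 42, led by cytochrome c1, CYC1, from 464 to 250 CPM (camera adjusted p = 0.00349; adjusted p = 0.327 with an estimated correlation). Autophagy and lysosome genes fell in 17 and rose in 7 of 32, with CTSA, CTSD and LAMP1 down and GABARAPL1 up (camera adjusted p = 0.0103; adjusted p = 0.0502 with an estimated correlation). DNA repair genes fell in 21 and rose in 6 of 35, with BRCA1 from 152 to 95.5 CPM and ATM, the damage kinase, from 129 to 180 CPM (camera adjusted p = 0.00677; adjusted p = 0.208 with an estimated correlation). Corepressor and acetyltransferase genes fell in 17 and rose in 4 of 29, with MTA2 and the acetyltransferase gene KAT2A lower and RCOR1 higher (camera adjusted p = 0.00328; adjusted p = 0.0497 with an estimated correlation).

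Several immune lists rose under the JeKo-1 label. Interferon-stimulated genes rose in 27 and fell in 2 of 37 (camera adjusted p = 7.47e-06). PARP14 rose from 9 to 256 counts over 3 libraries, and the antiviral genes IFIT3 and IFIT2 rose from 3.04 to 12.7 and from 1.21 to 8.30 CPM, while ISG15 fell from 19.4 to 13.1 CPM. NF-kB targets rose in 20 and fell in 4 of 24, with the activation marker CD83 up from 161 to 735 CPM and TNFAIP3, an NF-kB inhibitor gene, from 115 to 289 CPM (camera adjusted p = 3.63e-07; adjusted p = 0.0502 with an estimated correlation). RELB, IL10 and SOD2 fell within that list. Surface antigens used in therapy rose in 16 and fell in 3 of 22, with SLAMF7 from 13.4 to 51.7 CPM, CD22 from 224 to 449 CPM and the costimulator CD86 higher, against lower CD37 and CD79B (camera adjusted p = 0.00056; adjusted p = 0.0502 with an estimated correlation). MHC class II genes rose in 13 and fell in 2 of 16, including HLA-DOA and HLA-DRA, against lower RFXANK, one of their regulators (camera adjusted p = 0.000247; adjusted p = 0.0956 with an estimated correlation). Immediate early genes rose in 15 and fell in 1 of 18, with IER3 from 2.02 to 23.2 CPM and JUNB from 131 to 198 CPM (camera adjusted p = 0.000247; adjusted p = 0.0502 with an estimated correlation). Of 5 antiapoptotic BCL2 family genes 4 rose and 0 fell, among them BCL2A1 from 31.2 to 77.7 CPM (camera adjusted p = 0.00818; adjusted p = 0.0511 with an estimated correlation).

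Markers known from histone deacetylase inhibition rose in 12 and fell in 2 of 21 under the JeKo-1 label, where 6 of them had no count in any library, with the redox regulator TXNIP from 73.4 to 174 CPM and the synaptotagmin gene SYT11 from 16.9 to 66.6 CPM (camera adjusted p = 0.00349 and, over the 15 with a count, 1.97e-05; adjusted p = 0.0511 with an estimated correlation). Of 21 myeloid markers, fixed as signs of another cell type, 9 were tested, and 6 rose and 0 fell (camera adjusted p = 0.00589; adjusted p = 0.0502 with an estimated correlation). The integrin gene ITGAM rose from 2.42 to 24.2 CPM and CD33 from 0.34 to 4.76 CPM. LYZ, S100A8 and S100A9, abundant in myeloid cells, reached 3.46, 0.0237 and 0.309 CPM. The 6 that rose, LYZ among them (from 0.33 CPM), had a median of 4.11 CPM. Upper-quartile scaling turned 53.1% of calls higher into 64.9% and library-size scaling into 63.7%, the unfiltered length-scaled score gave 63.9%, and both scalings ended the BCL6 call, as did leaving out chidamide replicate 2 (edgeR adjusted p = 0.0516) or vehicle replicate 1 (0.104), no count filter and the length-scaled score (0.00195 to 1 over all its alternatives). HDAC1 passed as higher in 13 of 18 alternatives (adjusted p from 1.13e-06 to 0.163), the HDAC3 rise was lost without vehicle replicate 3 (0.0952, against 3.41e-06 to 0.0952 over its alternatives), and the oxidative phosphorylation call ended under library-size scaling (0.0505, against 4.14e-05 to 0.327).

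The second comparison asked the same of Granta-519. Here MYC rose, from 85.1 ± 1.03 to 123.5 ± 3.63 CPM (SD, n = 3), yet 51 of 60 MYC target genes fell. CDKN1A rose 2.07-fold to 241 ± 7.80 CPM and BCL6 3.91-fold from 15.8 ± 1.01 CPM. Neuronal genes and surface antigens rose as groups, and genes of DNA replication and the lysosome fell. MHC class II genes also rose and oxidative phosphorylation genes fell by camera, calls lost with an estimated correlation (adjusted p = 0.0975 for each). Of 15087 genes tested, 5970 were higher and 4725 lower, 10695 in all (edgeR's quasi-likelihood test, Benjamini-Hochberg), and 2740 were at least 2-fold higher against 364 lower.

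On the log2 scale MYC changed by 0.54 ± 0.05 (SE; edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p = 4.34e-15), CDKN1A by 1.05 ± 0.05 (edgeR adjusted p = 6.56e-27) and BCL6 by 1.97 ± 0.07 (edgeR adjusted p = 2.54e-32). BCL2 was already high in Granta-519 and rose from 596 ± 9.37 to 730 ± 39.5 CPM, 0.29 ± 0.04 on the log2 scale. CCND1 fell from 2114 ± 43.0 to 1747 ± 109 CPM, −0.28 ± 0.04. HDAC10 fell from 43.4 ± 1.46 to 26.3 ± 2.43 CPM (−0.72 ± 0.08; edgeR adjusted p = 1.85e-11), and HDAC2 rose by 0.25 ± 0.04. Changes of 0.06 ± 0.04 in HDAC1 and 0.10 ± 0.05 in HDAC3 did not pass (edgeR adjusted p = 0.173 and 0.102).

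The largest rise in Granta-519 was in FFAR2, the receptor for short-chain fatty acids, from 5 to 464 counts over 3 libraries (6.51 ± 0.35). CCR2, a chemokine receptor gene of monocytes, went from 10 to 792 counts (6.34 ± 0.26) and PTRF, the caveolar coat gene cavin, from 15 to 883 counts (5.93 ± 0.26). The semaphorin gene SEMA6B (5.45 ± 0.20), the GMP reductase gene GMPR (21 to 853 counts) and the splicing regulator gene HNRNPLL (5.25 ± 0.29) completed the 6. The largest falls included CCDC34 (−1.92 ± 0.10), COMMD9 (−1.79 ± 0.13), DNLZ (−1.78 ± 0.11), the estrogen receptor gene GPER1 (−1.74 ± 0.07) and KIAA0753, a centriolar gene (−1.74 ± 0.14). By edgeR's quasi-likelihood test each of these 11 had an adjusted p of 1.79e-16 or lower.

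Most growth lists in Granta-519 moved down although MYC itself was higher. MYC targets had a median log2 change of −0.50 (camera, Benjamini-Hochberg adjusted p = 1.03e-11), with the hexokinase gene HK2 from 191 to 90.5 CPM, CDK4 from 384 to 206 CPM and PA2G4 from 515 to 320 CPM. Only 5 of them rose: GNL3, NOP56, NPM1, RCL1 and SLC29A2, of which GNL3, NOP56 and NPM1 encode nucleolar proteins. DNA replication genes fell in 31 and rose in 6 of 45, with MCM7, the polymerase subunit gene POLD3 and the ligase gene LIG1 lower and TK1 higher (camera adjusted p = 4.24e-05). Cyclin and kinase genes fell in 15 and rose in 4 of 23, with CDK4, E2F8 and CCNA2 lower and CCND2 higher, from 5.63 to 19.8 CPM (camera adjusted p = 0.00488). Mitosis genes fell in 19 and rose in 9 of 39, with FOXM1, the mitotic transcription factor, from 135 to 78.6 CPM, and CENPE, a kinetochore motor gene, up from 110 to 145 CPM (camera adjusted p = 0.036; adjusted p = 0.329 with an estimated correlation). Ribosomal protein genes rose in 48 and fell in 2 of 75, by a median of 0.12, with RPL9 from 742 to 954 CPM (camera adjusted p = 0.0215; adjusted p = 0.661 with an estimated correlation).

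Oxidative phosphorylation genes fell in 33 and rose in 0 of 42 in Granta-519, with CYC1 from 237 to 90.1 CPM and the complex I gene NDUFS3 from 68.7 to 34.5 CPM (camera adjusted p = 4.73e-08; adjusted p = 0.0975 with an estimated correlation). Autophagy and lysosome genes fell in 20 and rose in 5 of 32, with LAMP1 and the proton pump gene ATP6V0D1 lower, while the cathepsin gene CTSB rose from 49.2 to 141 CPM (camera adjusted p = 0.000566). Heat shock genes fell in 11 and rose in 3 of 14, with HSPB1 from 213.5 to 113 CPM and BAG3 up from 5.12 to 16.9 CPM (camera adjusted p = 0.00881; adjusted p = 0.171 with an estimated correlation). Glycolysis genes fell in 13 and rose in 5 of 24, the neuronal enolase gene ENO2 rising from 11.1 to 49.9 CPM (camera adjusted p = 0.036; adjusted p = 0.347 with an estimated correlation). DNA repair genes fell in 18 and rose in 8 of 35, with the Fanconi anaemia gene FANCG from 47.4 to 17.2 CPM and BRCA2 up from 116 to 174 CPM (camera adjusted p = 0.036; adjusted p = 0.329 with an estimated correlation). Corepressor and acetyltransferase genes fell in 14 and rose in 5 of 29, with the scaffold gene SIN3A from 126 to 56.5 CPM and the bromodomain gene BRD2 up from 310 to 466 CPM (camera adjusted p = 0.041; adjusted p = 0.0975 with an estimated correlation).

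Markers of histone deacetylase inhibition rose in 18 and fell in 1 of 21 in Granta-519, with SYT11 from 9.43 to 121 CPM and the tubulin gene TUBB3 from 17.1 to 57.3 CPM (camera adjusted p = 6.15e-05). Of 38 neuronal genes 22 were tested, of which 17 rose and 1 fell (camera adjusted p = 6.81e-05). The synaptic adhesion gene NRXN2 rose from 1.54 to 30.8 CPM and the kinesin gene KIF5C from 1.71 to 25.5 CPM. Surface antigens rose in 17 and fell in 2 of 22, the chemokine receptors CXCR5 and CCR7 rising from 1.91 to 30.6 and from 56.8 to 139 CPM, against lower CD79B and CD70 (camera adjusted p = 0.000101). MHC class II genes rose in 12 and fell in 2 of 16, with HLA-DRA from 1552 to 2675 CPM (camera adjusted p = 4.24e-05; adjusted p = 0.0975 with an estimated correlation). NF-kB targets rose in 17 and fell in 5 of 24, with the chemokine gene CCL22 from 111 to 264 CPM and RELB down from 133 to 74.6 CPM (camera adjusted p = 0.00963; adjusted p = 0.239 with an estimated correlation). Interferon-stimulated genes rose in 23 and fell in 10 of 37, with the oligoadenylate synthetase genes OAS3 and OAS1 up from 3.21 to 34.5 and from 1.64 to 18.3 CPM and BST2 down from 160 to 90.1 CPM (camera adjusted p = 0.0406; adjusted p = 0.0975 with an estimated correlation). Of 21 myeloid markers 9 were tested, and 7 rose and 0 fell (camera adjusted p = 0.00344). CSF1R, the macrophage growth factor receptor gene, rose from 0.97 to 19.8 CPM and ITGAM from 24.9 to 79.3 CPM. By contrast, LYZ, S100A8 and S100A9 reached at most 0.19 CPM, against a median of 19.7 CPM for the 7 that rose.

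The interferon call ended with the replicate number as a block (adjusted p = 0.0799), without Granta-519 chidamide replicate 3 (0.0532) and without vehicle replicate 1 (0.06), with a range of 1.66e-08 to 0.0975 over its alternatives, while HDAC1 passed as higher in 3 and HDAC3 in 5 of 18 alternatives, the latter also without chidamide replicate 3 (0.0392; 0.00129 to 0.907 over all). The corepressor, mitosis, DNA repair and glycolysis calls ended under RLE scaling and a 1 CPM filter, the first 2 also with thinned libraries and without chidamide replicate 1 (0.0539 and 0.0533; 2.28e-07 to 0.0975 and 0.000296 to 0.33 over alternatives), and on the length-scaled score 40.4% of calls were higher in place of 55.8% with a mean score of 0.5 or more, but 58.6% with no filter.

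**Figure D2:**
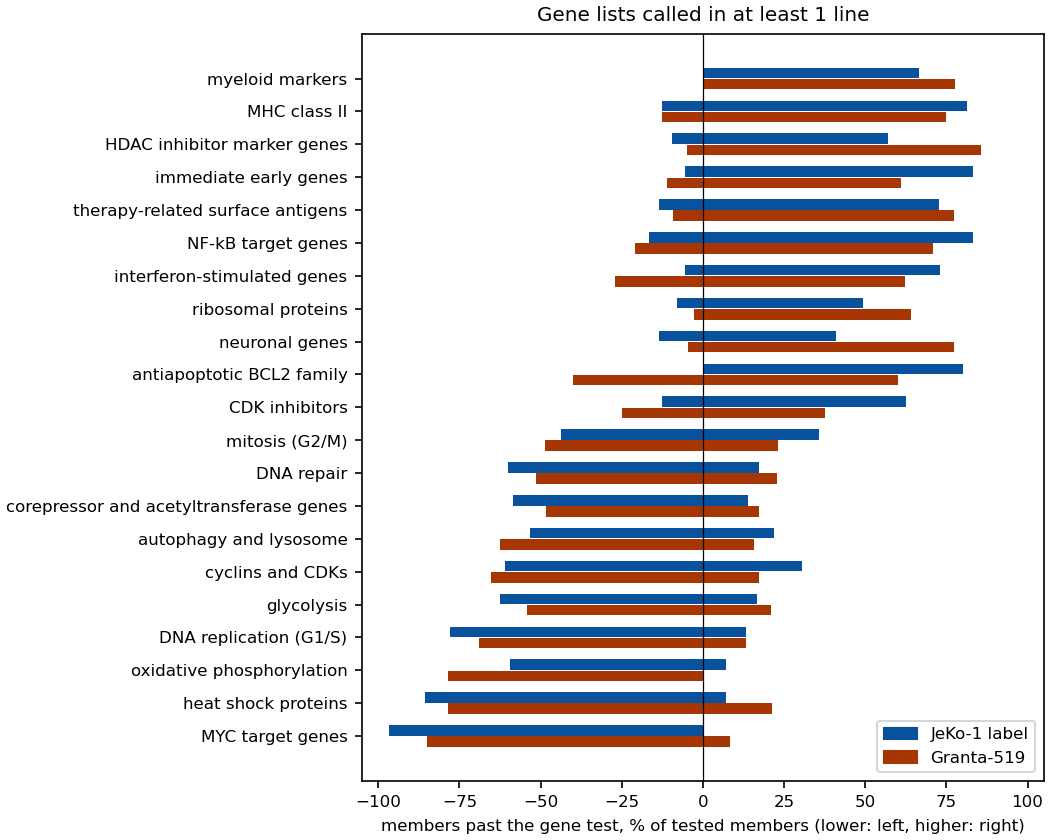
Percent of tested genes past the gene test in each of the 21 lists that camera called in at least 1 line, with lower genes to the left of 0 and higher genes to the right, for the JeKo-1 label (blue) and Granta-519 (orange). MYC targets reach farthest left, with 58 and 51 of 60 genes lower, and myeloid markers have no lower gene in either line.

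The next comparison asked whether the response differed between the lines. MYC moved in opposite directions, a difference of −1.24 ± 0.06 on the log2 scale (JeKo-1 label minus Granta-519; SE, edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p = 2.53e-23). BCL6 differed by −2.1 ± 0.08 (edgeR adjusted p = 2.36e-28), while BCL2 and CDKN1A rose more under the JeKo-1 label, by 0.55 ± 0.07 and 0.72 ± 0.07. KCTD15, the largest fall under the JeKo-1 label, rose in Granta-519 by 1.45 ± 0.21. B-cell transcription factor genes parted as a group, with 14 of 23 lower under the JeKo-1 label relative to Granta-519 and 1 higher. In all 5956 genes differed, 3015 with a more positive and 2941 with a more negative change under the JeKo-1 label, and 1419 of them by at least 2-fold.

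HDAC10 fell more under the JeKo-1 label, by a difference of −0.37 ± 0.12 (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.0075), and no difference passed for HDAC1, HDAC2 or HDAC3 (0.02 ± 0.06, 0.06 ± 0.06 and 0.05 ± 0.07), though each of the 3 passed in 5 of 24 alternatives, library-size scaling among them. The largest differences toward the JeKo-1 label were in genes with 0 vehicle counts there, such as MOB3B, a kinase activator gene, which reached 90 counts over 3 chidamide libraries, at least 25.7-fold higher. FBXO43, an inhibitor of the anaphase-promoting complex (45 counts), ZNF618 (at least 10.9-fold), the mitochondrial carrier gene SLC25A24 (at least 9.4-fold) and SLC44A5 (at least 8.3-fold) followed. Granta-519 already held 12.2 to 39.7 CPM of these 5 genes in vehicle. Toward Granta-519, the transcriptional repressor gene GFI1B went from 3 to 131 counts and the interleukin receptor gene IL7R from 6 to 128 counts over 3 libraries, against 14.4 to 18.2 and 42.1 to 42.8 CPM under the JeKo-1 label. In Granta-519 SEMA6B went from 28 to 1167 counts, CYP39A1, an oxysterol hydroxylase gene, from 1 to 27 counts, and ARHGEF4, an exchange factor gene, from 1644 to 2943 counts. The differences of SEMA6B (−7.42) and ARHGEF4 (−4.22) exceeded these rises. The rest was a fall under the JeKo-1 label, for ARHGEF4 at few counts.

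Among the lists, 13 differed between lines by camera, and 3 of these with an estimated correlation. B-cell transcription factors (camera, Benjamini-Hochberg adjusted p = 6.27e-09; adjusted p = 0.00423 with an estimated correlation) fell in 12 and rose in 7 under the JeKo-1 label and rose in 13 and fell in 6 in Granta-519, though neither line's own list test passed (camera adjusted p = 0.131 and 0.0947). In Granta-519 FOXO1, a transcription factor of B-cell development, rose from 4.25 to 29.1 CPM and PAX5, the B-cell identity factor, fell from 694 to 479 CPM. Under the JeKo-1 label TCF3 fell from 891 to 500 CPM and IRF8 rose from 272 to 439 CPM. Interferon-stimulated genes rose more under the JeKo-1 label (21 against 4 of 37; camera adjusted p = 8e-05; adjusted p = 0.0212 with an estimated correlation), as did the antiapoptotic BCL2 family (5 against 0 of 5; camera adjusted p = 0.000348; adjusted p = 0.0425 with an estimated correlation). MYC targets fell more there, in 45 against 2 of 60 (camera adjusted p = 7.85e-13; adjusted p = 0.0676 with an estimated correlation). Some of these lists already stood apart in vehicle. Interferon-stimulated genes were lower there under the JeKo-1 label in 29 and higher in 6 of 37 (camera adjusted p = 1.49e-05, and 0.0461 with an estimated correlation). MYC targets were higher in 45 and lower in 10 of 60 (camera adjusted p = 1.33e-05; adjusted p = 0.1975 with an estimated correlation). B-cell transcription factors were higher in 17 and lower in 3 of 23 (camera adjusted p = 0.00116; adjusted p = 0.0594 with an estimated correlation). Whether the starting level shaped the difference in response was not tested.

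The HDAC10 difference was lost without chidamide replicate 1 of the JeKo-1 label (adjusted p = 0.0606, against 0.000592 to 0.217 over its alternatives), under library-size scaling, without a count filter, with each line fitted alone and on the length-scaled score, and those of SEMA6B and ARHGEF4 without any of several JeKo-1 label libraries (chidamide replicates 1 and 3 and vehicle replicate 1 for both, and chidamide replicate 2 and vehicle replicate 3 for ARHGEF4), with adjusted p up to 1 and 0.173 over their alternatives. The number of differing genes was 2527 with each line fitted alone, and genes with more positive changes under the JeKo-1 label made up 50.6% of calls, but 70% under library-size scaling, 72.9% without a count filter and 65.5% on the filtered length-scaled score with 1 added (53.8% with no filter), where the differences of FBXO43, SLC25A24 and CYP39A1 also changed sign.

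The lines shared more of their response than independent lists of genes would. Across 15087 genes the log2 fold changes correlated with a Pearson r of 0.569 and a Spearman rho of 0.662, genes not being independent replicates. Both lines shared 3640 higher genes, against 2105 for independent lists, and 3372 lower genes, against 1471. At 2-fold or more they shared 1457 higher genes (470 for independent lists) and 129 lower genes (10). Opposite calls were fewer: 329 genes were higher under the JeKo-1 label and lower in Granta-519, 450 the reverse, and 18 moved oppositely by at least 2-fold in both. CDKN1A, BCL2, HDAC2, FMN1, LBH, CXCL10 and DNLZ were among the genes that moved the same way, and MYC and KCTD15 among those that did not. Without a count filter r was 0.372, and with DESeq2, also without that filter, it was 0.409.

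**Figure D3:**
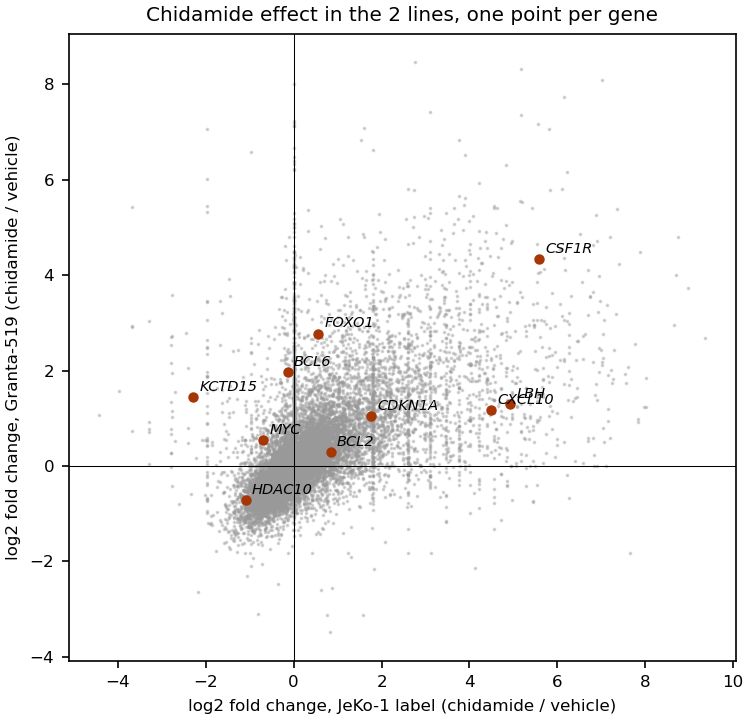
Log2 fold change after chidamide under the JeKo-1 label (x axis) against Granta-519 (y axis), 1 grey point for each of 15087 genes and 10 named genes in orange. The changes in the 2 lines correlate with a Pearson r of 0.569. MYC lies at −0.70 on x and 0.54 on y, KCTD15 at −2.29 and 1.45, and vertical stripes are genes with few counts under the JeKo-1 label.

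The last comparison set the 2 lines side by side in vehicle. MYC was higher under the JeKo-1 label, at 329 ± 8.48 against 85.1 ± 1.03 CPM (SD, n = 3), and BCL2 far higher in Granta-519, at 596 ± 9.37 against 23.5 ± 0.61 CPM. BCL6 was higher under the JeKo-1 label, at 234 ± 10.5 against 15.8 ± 1.01 CPM. CDKN2A, the tumour suppressor gene of p16, stood at 114 ± 5.35 CPM under the JeKo-1 label and had 0 counts in all Granta-519 libraries. The B-cell homing receptor gene CXCR5 (106 against 1.91 CPM), CDK6 (13184 against 369 counts over 3 libraries) and FOXO1 (94.8 against 4.25 CPM) were also higher under the JeKo-1 label.

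Toward Granta-519 the largest differences among list genes were in SOX11 and CCND1, given above, and in the small heat shock gene HSPB1, with 213.5 ± 3.14 CPM against 1 count in 3 libraries. The ectodysplasin receptor gene EDA2R followed, with 26.7 ± 0.32 CPM against 0 counts, then SDC1, the plasma-cell marker syndecan, with 91.6 ± 5.89 CPM against 1 count. In all 12038 genes differed, 5350 higher and 6688 lower under the JeKo-1 label (edgeR's quasi-likelihood test, Benjamini-Hochberg), of which 1932 and 3969 by at least 2-fold. Each line was a single line, so the test covers the spread of these libraries only.

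Chidamide also raised the number of genes that were counted at all. Under the JeKo-1 label 16889 to 17070 genes had at least 1 count after chidamide, against 14439 to 15029 in vehicle, and in Granta-519 18766 to 18790 against 17304 to 17572. In all 3 chidamide and no vehicle library, 749 genes were counted under the JeKo-1 label and 360 in Granta-519, whereas 8 and 16 genes were counted in all vehicle and no chidamide library. The neuronal microtubule gene MAP2 was one, with 0 and 165 counts over 3 libraries under the JeKo-1 label, at least 47.1-fold higher.

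**Figure D4:**
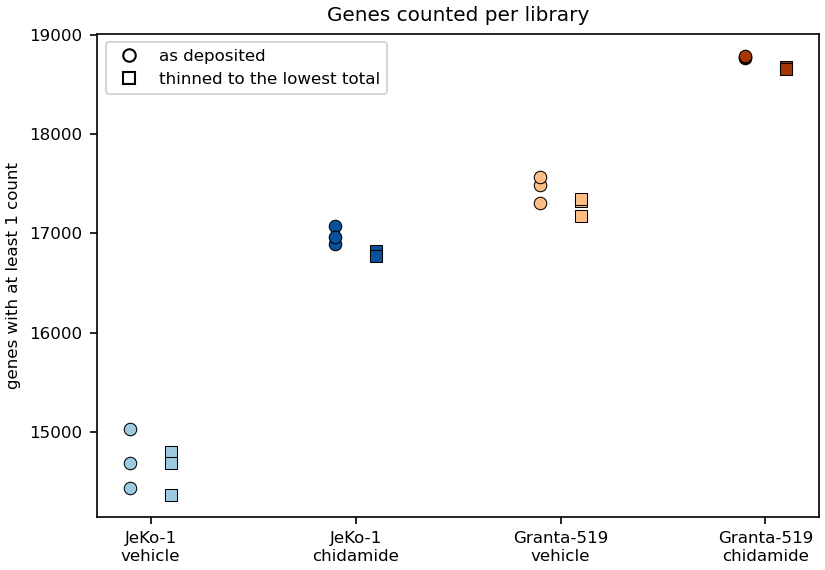
Number of genes with at least 1 count in each of the 12 libraries by line label and treatment, as deposited (circles) and after thinning to the lowest library total (squares); the axis does not start at 0. Every chidamide library lies above every vehicle library of its line, and thinned libraries keep a gap of 1977 genes under the JeKo-1 label and 1305 in Granta-519.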

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

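Tests chosen only after their results were seen were those of lost CCND1 reads, of exchanged line labels, of scaling for MYC, of myeloid cells and of lists without uncounted genes; the others were written down before. The genes and lists given first were singled out because the chidamide effect differed between the lines in the test of the difference itself, as it did for 5956 genes by edgeR's quasi-likelihood test. The missing CCND1 and SOX11 counts and the number of genes counted were noticed in the data. Of 100 drawn from the 200 possible splits of the libraries within each line, 2 gave as many, the real one and one with 10889 genes. That split exchanges the treatment labels in one line, so it turns the shared response into a difference. The 80 splits that mixed treatments in both lines gave 0 genes, but mixing removes the effect whose difference is tested, so these splits do not bear on chance as the source of the difference.

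Differences are the log2 change under the JeKo-1 label minus that in Granta-519. Among the fixed genes these were MYC (−1.24), BCL2 (0.55), the germinal-centre repressor BCL6 (−2.1), CCND1 (3.11), the p21 gene CDKN1A (0.72) and HDAC10 (−0.37). Among the largest were the kinase activator gene MOB3B (6.85), FBXO43 (6.62), ZNF618 (6.54), SLC44A5 (6.41) and the mitochondrial carrier gene SLC25A24 (6.29). In the other direction stood the semaphorin gene SEMA6B (−7.42), the repressor gene GFI1B (−5.03), the interleukin receptor gene IL7R (−4.39), CYP39A1 (−4.24) and ARHGEF4 (−4.22). These 10 genes had few or 0 counts in some group, so their fitted values depend on the prior count that edgeR adds and are not bounds. The same holds for CCND1, at 0.123 CPM in vehicle under the JeKo-1 label. Its log2 change there ran from 0.055 to 2.99 over 18 alternatives and passed the threshold in 16. Of 348 further named genes 227 passed the test of the difference, 106 with a more positive change under the JeKo-1 label and 121 with a more positive change in Granta-519.

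Among the lists, MYC targets (camera, Benjamini-Hochberg adjusted p = 7.85e-13; adjusted p = 0.0676 with an estimated correlation) and DNA replication genes (0.0103; adjusted p = 0.161 with an estimated correlation) changed more negatively under the JeKo-1 label. So did genes of B-cell receptor signalling, where 20 of 30 were lower and 5 higher relative to Granta-519 (3.69e-06; adjusted p = 0.104 with an estimated correlation), and B-cell transcription factors (6.27e-09; adjusted p = 0.00423 with an estimated correlation). MHC class II genes (0.00509; adjusted p = 0.275 with an estimated correlation) and neuronal genes (0.0083, and 9.9e-05 over the 18 of 22 with a count in both lines; adjusted p = 0.104 with an estimated correlation) also rose less there. More positive changes under the JeKo-1 label were found for the antiapoptotic BCL2 family (0.000348; adjusted p = 0.0425 with an estimated correlation), CDK inhibitors (0.0138, and 0.00119 over the 5 of 8 with a count in both lines; adjusted p = 0.118 with an estimated correlation) and p53 targets (0.0327; adjusted p = 0.161 with an estimated correlation). The same direction held for interferon-stimulated genes (8.00e-05; adjusted p = 0.0212 with an estimated correlation), NF-kB targets (1.91e-05; adjusted p = 0.104 with an estimated correlation), oxidative phosphorylation genes, 20 of 42 (0.000348; adjusted p = 0.294 with an estimated correlation), and immediate early genes (0.00545; adjusted p = 0.104 with an estimated correlation).

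MYC moved down under the JeKo-1 label and up in Granta-519. Scaling was argued against, since the difference nearest 0 over RLE, upper-quartile and library-size scaling was −1.10. Depth was argued against too, since it was −1.25 with all libraries thinned to the lowest total. Among what stays open is a difference in biology between the cell cultures, for which MYC offers a hypothesis only. The line is a group of the design but each line is a single line, so this was not tested. Other sources of the difference were not tested either.

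Libraries labelled JeKo-1 held almost no CCND1 or SOX11, genes known in that line. A loss of CCND1 reads in the authors' counting was argued against by 2114 CPM in Granta-519 vehicle libraries of the same table. An exchange of labels between the lines was not tested by these counts, since the lower vehicle mean of 0.123 CPM is the pattern itself, and only the background that both lines carry CCND1 speaks against it. Cells of another B-cell line under this label could also account for it: over 13 germinal-centre genes the median vehicle difference was 0.50, with 7 higher and 2 lower, short of the value of 1 set in advance, and over 12 genes of SOX11-positive cells it was −6.76, with 10 lower and 1 higher, 2 of them with 0 counts in those vehicle libraries, well past the limit set for it. Because only the second list passed its limit, this explanation stays open, and a culture of JeKo-1 that lost both genes stays open as well.

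More genes were counted after chidamide in both lines. A difference in depth was argued against, since thinned libraries kept a gap of 1305 genes in Granta-519, the smaller of the lines. Carry-over of reads from Granta-519 was argued against: 18 genes abundant in Granta-519 reached a median of 0.0175% of their level there under the JeKo-1 label, whereas 517 newly counted genes reached 26.2%. Myeloid cells in the cultures were argued against in Granta-519, where LYZ, S100A8 and S100A9 reached at most 0.187 CPM while the 7 risen myeloid markers had a median of 19.7 CPM. Under the JeKo-1 label LYZ rose from 0.33 to 3.46 CPM and is itself among the 6 risen markers. Their median of 4.11 CPM therefore rests partly on LYZ, so this comparison cannot decide. S100A8 and S100A9 stood at 0.0237 and 0.309 CPM, which goes against cells rich in S100A8 and S100A9. Other myeloid cells stay possible there. Low transcription from many genes, an effect that may follow from blocked deacetylation, was not tested in either line. Other sources of such low counts were not tested either.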

How the results depend on the processing

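Thinning and list tests without uncounted genes were chosen after seeing the data; the other tests here were set before. Of 499 results for named genes, 398 kept their side of the threshold under every alternative that tested them, and their direction wherever they passed. The 2-fold threshold was applied only to numbers of calls and is not among these alternatives. Alternatives whose filter dropped a gene do not count for it. In at least 1 alternative 93 lost a call, 6 gained one and 11 changed sign. Of 70 list results these numbers were 19, 24, 26 and 1. Changes of sign or direction between results that both missed the threshold were not counted. The median of mitosis genes under the JeKo-1 label, for example, ran from −0.0961 to 0.0579 over alternatives. MYC changed by −0.71 to −0.54 under the JeKo-1 label and by 0.43 to 0.64 in Granta-519, past the threshold in each of 18 alternatives, though it does not reach 2-fold in either line. A 2-fold threshold left 2987 genes under the JeKo-1 label (2587 higher, 400 lower), 3104 in Granta-519 (2740 and 364), 1419 differing in response (899 and 520) and 5901 between lines in vehicle (1932 and 3969). With each line fitted alone 2527 genes differed in response (1515 and 1012), in fits whose filter, scaling and residual degrees of freedom also changed. The test changed too: the effects of the lines were compared by a t-test with the residual degrees of freedom of 1 line. How much each of these lowered the number was not tested. For the other changes in this part the cause was not tested, except where stated.

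Of the lists, 18 were called in each line; an estimated correlation left 4 under the JeKo-1 label and 8 in Granta-519, and fry, which does not compare a list with other genes, called 32 and 31. Without genes that had no count in the line, 18 lists were called in each line and 13 in the difference, and no list changed its call. For proapoptotic genes in Granta-519, with a median of −0.10 and a downward camera direction, fry gave an upward one (fry adjusted p = 0.00221). Fry also turned the camera direction of proapoptotic genes under the JeKo-1 label (fry adjusted p = 0.584). In Granta-519 it turned those of histone deacetylase, MYC network and MHC class I genes (fry adjusted p = 0.919, 0.689 and 0.955). These lists passed in neither test.

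Without a count filter 4669 genes had a more positive and 1733 a more negative change under the JeKo-1 label; the more negative ones were 1919 under library-size scaling and 1863 and 1713 on the filtered length-scaled score with 1 and 0.1 added, but 3741 on the unfiltered one. In Granta-519 2999 and 2965 genes were higher on the filtered score and 6718 on the unfiltered one, and both of these differ from the counts in test and scaling as well; on the filtered score 2133 were higher in both lines. Pearson r between lines was 0.372 without a filter, 0.581 with a 1 CPM filter and 0.678 on the filtered length-scaled score. With DESeq2, also run without a filter, r was 0.409. Leaving out each library in turn gave r from 0.543 to 0.556, with more genes tested because the filter then asks for fewer libraries; calls ranged from 9560 to 9778 under the JeKo-1 label, 10180 to 10388 in Granta-519, 5504 to 5867 for the difference and 11824 to 11987 in vehicle. The median log2 change of all genes under the JeKo-1 label moved from 0.04 to 0.19 with upper-quartile and 0.17 with library-size scaling.

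Sign changes under the JeKo-1 label were small: BCL6 (0.0074), RPL14 (0.034), RPL19 (0.060) and RPLP2 (0.060) with upper-quartile scaling, the 3 ribosomal genes (0.019, 0.046 and 0.046) with library-size scaling, and on the length-scaled score RPL14 at 0.022, RPL19 at 0.050 and RPLP2 at 0.048 with 1 added, filtered or not, and RPLP2 at 0.049 with 0.1 added. In Granta-519 SHMT2 changed sign with upper-quartile scaling (0.0047), and MKI67 (−0.0198) and PRKDC (−0.0144) without a filter. All sign changes listed here are those where the main result or the alternative passed the threshold. Genes that missed it in both, whatever their sign, are not listed. The difference between lines changed sign on the score with 1 added for FBXO43 (−0.0623), SLC25A24 (−0.00654) and CYP39A1 (0.0734), with or without its filter, and for MOB3B (−0.256) without it, where an added value of 1 outweighs such low levels.

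Replicate numbers did not pair the libraries: same-number correlations of deviations were 0.153, 0.184 and −0.061 under the JeKo-1 label and 0.204, 0.091 and 0.32 in Granta-519, and not every library correlated best with its own number. The replicate block gave 10143, 10776, 6234 and 11121 calls for the 2 lines, the difference and the lines in vehicle, and it ended the interferon call in Granta-519. Thinned libraries gave 9777, 10453, 5755 and 11806. Genes with few counts are limited by depth.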

Other observations

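The lists and splits in this part were planned, and the relation with gene length was examined only after the data were seen. Among lists that camera called in neither line, apoptosis genes moved both ways. Of 27 proapoptotic genes 10 rose and 13 fell under the JeKo-1 label and 11 rose and 11 fell in Granta-519 (camera, Benjamini-Hochberg adjusted p = 0.795 and 0.77). BMF, a BH3-only killer gene, rose from 7.57 to 28.6 CPM and from 12.0 to 48.4 CPM, whereas BAX, the pore-forming effector, fell from 127 to 60.9 CPM and from 142 to 77.7 CPM. Inhibitors of apoptosis rose in 4 and fell in 2 of 8, and rose in 4 and fell in 1 (0.474 and 0.353), with BIRC3 up from 831 to 1303 CPM and from 241 to 573 CPM. Of 28 p53 targets 11 rose and 7 fell, and 9 rose and 13 fell (0.3 and 0.321), the antiproliferative gene BTG2 rising in both lines. Of 13 genes of the MYC network 4 rose and 6 fell, and 5 rose and 7 fell (0.479 and 0.678), with MYCL up from 3.90 to 24.0 CPM and from 6.34 to 18.2 CPM, and MXI1, a MYC antagonist, up in both. Of 11 histone deacetylase genes 5 rose and 3 fell, and 2 rose and 3 fell (0.466 and 0.77): HDAC9 rose from 6.91 to 40.3 CPM under the JeKo-1 label, and HDAC7 fell there from 264 to 188 CPM but rose in Granta-519 from 31.6 to 54.2 CPM. In the corepressor complex of REST, the silencer of neuronal genes, 4 of 9 rose and 2 fell in each line (0.727 and 0.678), and REST itself fell by 0.23 and by 0.31 on the log2 scale, a fall lost under the JeKo-1 label in 5 of 18 alternatives: upper-quartile and library-size scaling and the 3 forms of the length-scaled score (adjusted p up to 0.276).

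B-cell receptor signalling genes rose in 12 and fell in 14 of 30 under the JeKo-1 label and rose in 19 and fell in 8 in Granta-519 (camera adjusted p = 0.269 and 0.103). There PLCG2, the phospholipase of the pathway, rose from 219 to 462 CPM and SYK, an early kinase of it, from 259 to 474 CPM, while AKT1 fell in both lines. Plasma-cell genes rose in 7 and fell in 5 of 15, and rose in 7 and fell in 7 (0.579 and 0.77). MHC class I genes rose in 7 and fell in 4 of 17, and rose in 8 and fell in 8 (0.419 and 0.77), with B2M, the light chain, up from 617 to 846 CPM and from 2389 to 3263 CPM. Genes of the integrated stress and unfolded protein responses rose in 11 and fell in 9 of 26, and rose in 14 and fell in 8 (0.428 and 0.321). HERPUD1, a gene of protein degradation at the endoplasmic reticulum, rose from 93.8 to 183 CPM and from 106 to 231 CPM. Cholesterol synthesis genes rose in 5 and fell in 9 of 21, and rose in 12 and fell in 7 (0.448 and 0.77), with HMGCS1, an early enzyme of the pathway, up in both. Of 8 tested T-cell and natural killer markers 3 rose and 0 fell, and 6 rose and 0 fell (0.269 and 0.0701), LCK rising from 19.8 to 47.0 CPM and from 22.5 to 56.1 CPM. Of 11 epithelial and stromal markers 5 rose and 0 fell, and 7 rose and 1 fell (0.109 and 0.168). Neuronal genes under the JeKo-1 label rose in 9 and fell in 3 of 22, of which 19 had a count there (0.269, and 0.179 over those 19), ribosomal protein genes there rose in 37 and fell in 6 of 75 (0.0787, called in 7 of 14 alternatives: RLE and library-size scaling, the replicate block, thinned libraries, fry, and without vehicle replicate 1, at 0.024, or 2, at 0.00721, over a range of 0.000158 to 0.671), and mitosis genes rose in 14 and fell in 17 of 39 (0.466). In Granta-519 immediate early genes rose in 11 and fell in 2 of 18 (0.0519, called by fry and without chidamide replicate 3, at 0.0418, over a range of 3.17e-06 to 0.234), antiapoptotic BCL2 family genes rose in 3 and fell in 2 of 5 (0.77), and CDK inhibitors rose in 3 and fell in 2 of 8 (0.77). Mean or median and camera direction differed in sign for the MYC network and proapoptotic genes under the JeKo-1 label, and for histone deacetylase, proapoptotic, antiapoptotic and plasma-cell genes in Granta-519. Of lists too small to test, the histone gene HIST1H2AG rose from 0.62 to 1.52 and from 0.97 to 1.91 CPM.

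Longer genes changed more positively than shorter ones. Across 14031 of the tested genes (93%), the log2 change correlated with genomic span by a Spearman rho of 0.2 under the JeKo-1 label and 0.176 in Granta-519, and by 0.23 to 0.351 and 0.206 to 0.307 within 4 classes of expression level; genes are not independent replicates. The tenth of genes with the shortest span had median changes of 0.00 and 0.03 and the tenth with the longest 0.61 and 0.52. With exonic length rho was 0.063 and 0.075.

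With 3 libraries against 3 there are 10 splits, too few for a share under 0.05, so only the values are given. The real split gave 10016, 10695 and 12038 genes for the JeKo-1 label, Granta-519 and the lines in vehicle, 1 of the 10 splits in each case, and the highest other split gave 0 genes by edgeR's quasi-likelihood test. For lists the real splits gave 18 and 18, also 1 of 10, and the other splits, each of which still parts the treatments 2 to 1, at most 15 and 17, with medians of 9 and 10. The agreement of r = 0.569 was reached by 1 of 100 drawn splits, the highest other being 0.467, but mixing treatments within a line weakens the effects that are compared, so these splits do not bear on chance as the source of the agreement.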
